A study of Mus musculus with 24 samples.

How the data were processed

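The libraries came from ID8 p53-/- cells seeded in wells, adherent or in ultra-low attachment plates, treated 24 hours after seeding and harvested 24 hours later, per the labels' protocols. The same protocols state that dead cells were removed from the ULA wells, that RNA was extracted with TRI Reagent and Direct-zol columns, and that poly-A libraries were sequenced on a NovaSeq X. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to GRCm38 (mm10) with HISAT2, handled with SAMtools and counted with featureCounts of Subread 2.1.1, and expression was analysed with DESeq2. The versions of the other tools are not given in the sources used here.

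The deposited files hold raw gene counts, 1 table per library. Per the file headers, featureCounts v2.1.1 counted exon features in paired-end mode without a strand setting, without multi-mapping reads and without the option that counts a pair once, so each mate adds 1 to a count. Even numbers made up 61.3% to 67.2% of counts from 1 to 20. Genes that overlap another gene or its antisense partner, and near-identical copies such as Tgtp1 and Tgtp2, are therefore less certain. No normalised table of the authors was used. The tables list 31062 features, of which 9 are transgenes. Mouse identifiers were paired with symbols for 30934 features, 119 had no symbol, and 28 symbols were shared by several identifiers. Positions were taken from the GENCODE M21 annotation of GRCm38, which held 31011 of the features. No count in any library was found for 7969 features.

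Totals per library ran from 33494774 to 63154942 counts. Genes passed edgeR's filterByExpr with a minimum count of 10 and the 8 groups as design, which kept 14622 genes holding at least 99.97% of the counts of every library. One model was fitted to all 24 libraries with a mean per group, no covariates, TMM factors (0.958 to 1.054) and robust quasi-likelihood dispersion, in edgeR 4.0.16 under R 4.3.3. It left 16 residual degrees of freedom, a common biological coefficient of variation of 0.0771 and a median prior of 17.6 degrees of freedom. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene is called, and said to rise, fall or differ, at an adjusted p under 0.05. Log2 fold changes are given with the standard error of the fitted contrast and 95% intervals come from the same fit. CPM values are group means scaled by the TMM-adjusted library size.

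The comparisons were IFN-gamma against PBS in each line and culture, ULA against adherent in PBS in each line, Ifngr1-KO against sgNTC in PBS in each culture, and 3 interactions (the response in ULA minus that in adherent sgNTC cells, and the response in Ifngr1-KO minus that in sgNTC cells in each culture). These, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The difference between the lines in the effect of culture was added afterwards.

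The rule named the 8 genes with the largest change each way in a comparison (6 for interactions) among called genes with a mean of at least 5 CPM in 1 group and no overlap between the 3 libraries of 1 group and the 3 of the other, a pattern chance gives in 10% of unchanged genes. Predicted gene models were left out, and interactions were ranked without the overlap condition. It added up to 4 called members with the smallest adjusted p of each list, and Ifngr1 and Trp53 as values. Some genes the rule selects are not reported here. A gene without any count in a group is given as a fold against a floor of 3 counts over the libraries of that group. As each mate adds 1 to a count, 3 counts can come from fewer than 3 read pairs, so this fold is not a strict lower bound. Floors and intervals of such values cover counting error only.

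Fixed lists of genes numbered 37, with 681 entries, written from general knowledge. They cover IFN-gamma receptor and JAK-STAT signalling, interferon-inducible GTPases, MHC class I and class II presentation, chemokines, immune checkpoints, the type I interferon signature, NF-kB targets, complement, death pathways, ferroptosis and glutathione, mitosis, DNA replication, CDK inhibitors and cyclin D, cholesterol synthesis and fatty acid metabolism. The others are hypoxia and glycolysis, the integrated stress response, ER chaperones, extracellular matrix, integrins, YAP targets, SRF targets, epithelial and mesothelial, mesenchymal, stemness, immediate early, heat shock, p53 target, autophagy and lysosome, oxidative phosphorylation and mitochondrially encoded genes. The last 5 hold markers of macrophages, lymphocytes, endothelium, fibroblasts and pericytes, and erythroid cells. No feature matched 6 entries (Gbp11, H2-T10, Ifi30, Cxcl11, Mx2 and C5). The 33 lists with at least 5 tested members in a comparison were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 33, and again with the correlation estimated from the residuals. Fry was run on the same lists.

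The alternatives tried were RLE size factors in edgeR, library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, and each library left out in turn. Counts halved and rounded were added after the data were seen. Each comparison was also repeated on other splits of its libraries, 10 where 6 libraries were compared and 100 drawn for interactions. The methods were tested on simulated counts drawn from the real means and library sizes. In these 200 genes were changed, drawn at random among those with a mean of at least 1 CPM in the compared groups. In the simulated sgNTC adherent comparison edgeR recovered 85.1% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes, and in the simulated ULA minus adherent interaction 65.7%, 79.1% and 98.5%. Between 2.5% and 7.4% of its calls were false over the comparisons simulated, against 3.8% to 11.7% for DESeq2, on counts that follow edgeR's own estimates of spread. No unchanged list was called, but genes were simulated independently, so this does not test list calls under correlation among members.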

Results

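Gene expression was measured by poly-A RNA sequencing in 24 libraries of ID8 p53-/- cells, a mouse ovarian cancer line without intact p53. Each library came from 1 of a pair of derivatives, a line edited at Ifngr1, which encodes the ligand-binding chain of the interferon-gamma (IFN-gamma) receptor, or the control line labelled sgNTC. Cells grew attached to plastic (adherent) or detached in ultra-low attachment (ULA) wells, and received IFN-gamma at 100 ng/ml or PBS for the last 24 of 48 hours. The 8 groups held 3 libraries each, numbered as biological replicates by the labels, so p-values measure the spread between those cultures. Dead cells were removed from ULA wells and not from adherent ones, and each genotype is represented by 1 line. A difference between cultures therefore also carries that handling step, and a difference between genotypes also carries any other difference between the lines.

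Each library held 33494774 to 63154942 counts, with both mates of a read pair counted. Totals were 33494774 to 55947189 in adherent sgNTC libraries, 38435496 to 53261450 in adherent Ifngr1-KO libraries, 37063763 to 63154942 in ULA sgNTC libraries and 38185599 to 49849934 in ULA Ifngr1-KO libraries. The most abundant gene, mt-Co1, took 1.41% to 2.96% of the counts, and 14622 genes were tested. Mitochondrially encoded genes held 1.96% to 2.45% of counts in adherent Ifngr1-KO libraries and 2.49% to 2.94% in adherent sgNTC libraries. In ULA libraries their share was 3.31% to 3.87% in Ifngr1-KO and 5.09% to 6.12% in sgNTC cells. The first principal component held 46.5% of the variance and parted adherent from ULA libraries, and the next held 24.9% and parted the lines. Each also carried the other factor. On the first, adherent Ifngr1-KO libraries lay at -75.33 to -70.75 and adherent sgNTC libraries at -34.08 to -27.01. On the second, Ifngr1-KO libraries lay at 12.67 to 18.95 in adherent and 58.9 to 64.24 in ULA culture. These shares of variance therefore do not measure culture and line apart. The adherent Ifngr1-KO PBS replicate 3 library lay apart from the other 2 of its group on the fourth component, which held 1.7%, at -36.19 against 14.66 and 12.96. By a chi-square per gene between libraries of a group it stood at 21.18 and 20.91 from the other 2, which stood at 7.75. The ULA Ifngr1-KO IFN-gamma replicate 2 library lay further from its group, at 21.87 and 27.52 against 7.94.

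**Figure D1:**
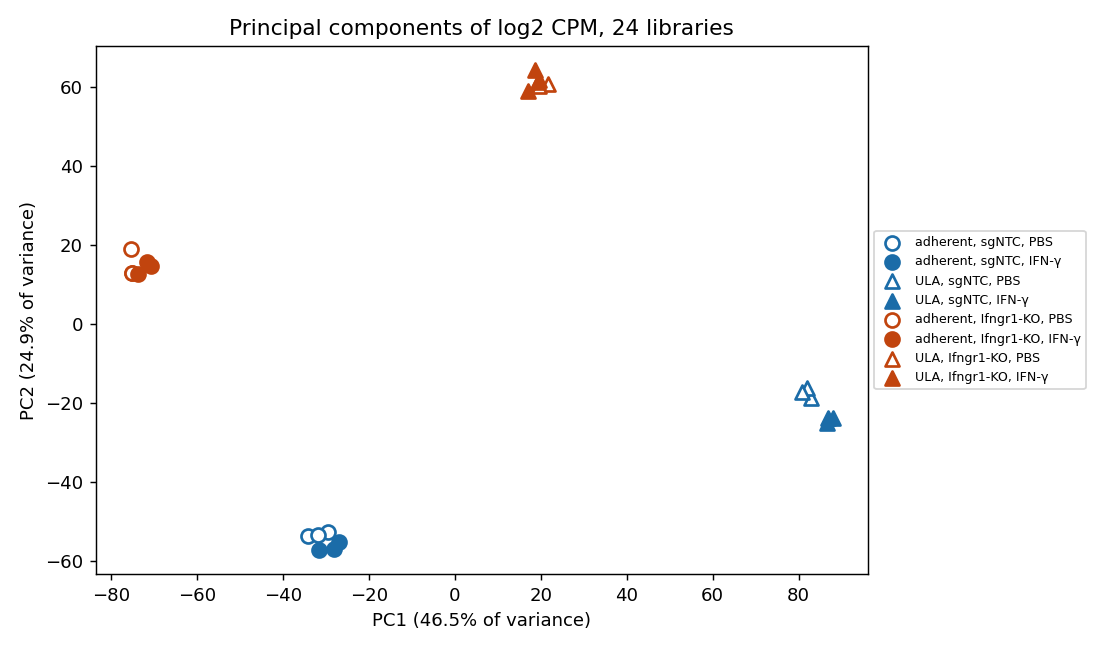
Principal components of the log2 CPM (counts scaled to library size) of the tested genes, 1 point per library, coloured by group. The horizontal axis (46.5% of variance) separates ULA from adherent libraries and the vertical axis (24.9%) separates the lines. Each axis also carries part of the other difference.

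The targeted gene was lower in every Ifngr1-KO library than in every sgNTC library. Ifngr1 (ENSMUSG00000020009, GRCm38 chromosome 10, 19591949 to 19610229, plus strand) stood at 13.3 to 17 CPM in the 12 Ifngr1-KO libraries and at 31.7 to 48.1 CPM in the 12 sgNTC libraries. In PBS its mean was 15.6 ± 0.977 CPM (SD, n = 3) against 43.2 ± 1.98 CPM in adherent cells, and 14.7 ± 0.715 against 35.6 ± 3.39 CPM in ULA cells. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for every gene below, this was a log2 fold change of -1.46 ± 0.08 (SE, adjusted p = 2.69e-16) in adherent cells. In ULA cells it was -1.27 ± 0.08 (adjusted p = 7.18e-15). An edited gene can still be transcribed, and 36.3% and 41.3% of the sgNTC level remained. IFN-gamma did not move it past the threshold in any of the 4 settings. Trp53 transcripts were still counted, at 32.4 to 35.1 CPM as group means in adherent and 14.7 to 19.4 CPM in ULA cells. Cas9, which the annotation carries as a transgene, stood at group means of 1110 to 2030 CPM in sgNTC and 69.7 to 104 CPM in Ifngr1-KO cells (log2 fold change -4.11 ± 0.08 in adherent PBS cells, adjusted p = 2.73e-24).

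**Figure D2:**
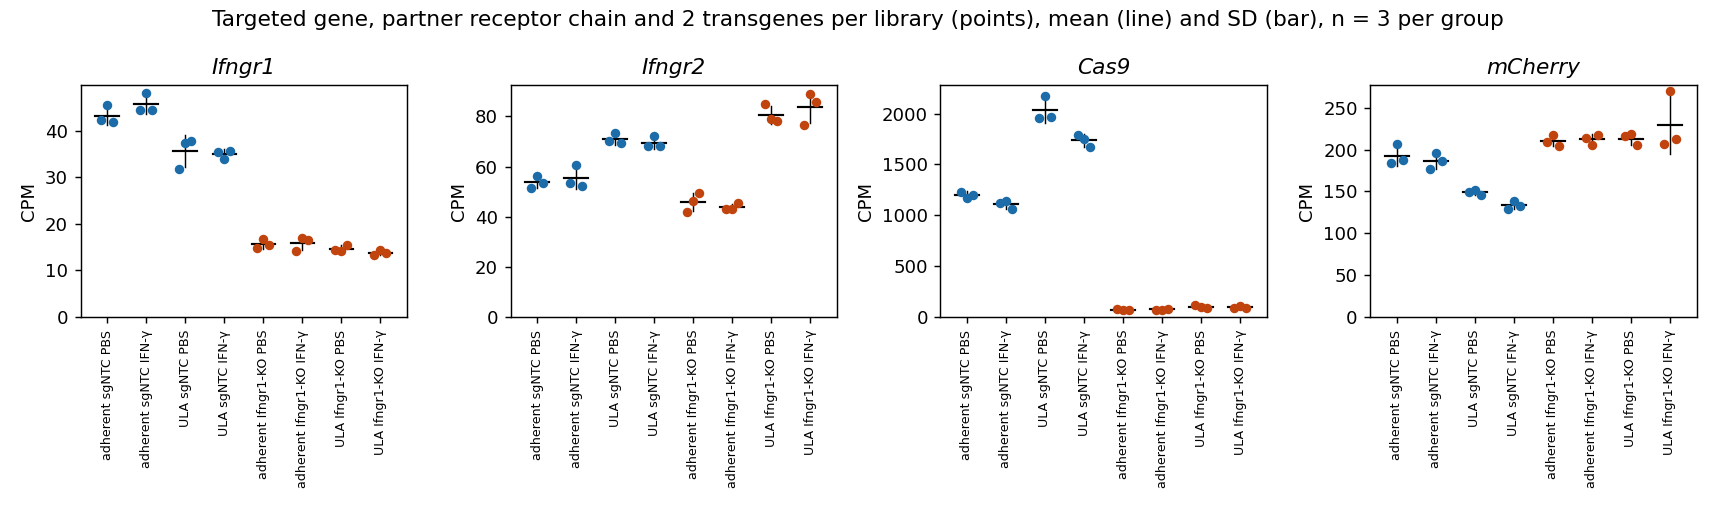
CPM of Ifngr1, Ifngr2, Cas9 and mCherry in each of the 24 libraries by group, with group means and SD. Ifngr1 lies at 13.3 to 17 CPM in Ifngr1-KO and at 31.7 to 48.1 CPM in sgNTC libraries.

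The effect of IFN-gamma on attached receptor-competent cells was mainly a rise of interferon genes. The most strongly raised were GTPases that act against intracellular pathogens, Irgm2 (log2 fold change 2.47 ± 0.39, adjusted p = 0.00452, 12.8 against 2.36 CPM, n = 3 each), Gbp2 (2.41 ± 0.35, 0.00198, 16.3 against 3.12 CPM) and Igtp (2.36 ± 0.43, 0.0164). Tap1, which carries peptides to MHC class I, rose from 2.59 to 11.2 CPM (2.12 ± 0.33, adjusted p = 0.00396). The transcription factor Irf1 rose from 47.6 to 74.5 CPM (0.65 ± 0.09, 0.000246). Among 46 genes called, 43 rose, 15 of them more than 2-fold, and 28 of those 43 were members of the 5 interferon lists. DESeq2 called 83, a fit of the compared groups alone 101, and 175 were called without a filter on low counts. The 3 that fell were the collagen receptor Mrc2 (-0.58 ± 0.13, adjusted p = 0.0278), the glycolytic enzyme Pfkm (-0.31 ± 0.06, 0.01) and the scaffold protein Iqgap2 (-0.24 ± 0.05, 0.0254).

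In adherent sgNTC cells, 8 of 17 interferon-inducible GTPases rose and 15 of 17 when adjusted over the list alone (camera adjusted p = 9.3e-45). Class I antigen presentation followed with 9 of 20 raised and 14 adjusted over the list alone (1.57e-42), among them the immunoproteasome subunit Psmb10 (0.92 ± 0.12, adjusted p = 3e-05) and the peptidase Erap1 (0.63 ± 0.08, 3e-05). The type I interferon signature had 8 of 29 raised and 16 adjusted over the list alone (2.09e-41), including the antiviral membrane protein Ifitm3 (0.86 ± 0.10, adjusted p = 1.98e-05). Of 16 receptor and JAK-STAT genes 3 rose, 4 adjusted over the list alone (2.22e-07), with Irf9 at 0.78 ± 0.11 (adjusted p = 9.05e-05). Of 26 death pathway genes 2 rose, such as Casp12 at 0.80 ± 0.13 (adjusted p = 0.000863), and camera called the list (0.00539). These 5 list calls held with an estimated correlation. The checkpoint list rose and the hypoxia and glycolysis and matrix lists fell by camera only with the preset correlation, at adjusted p = 0.0646, 0.675 and 0.252 with an estimated correlation, and no member of these 3 passed. The checkpoint ligand Cd274 went from 5.62 to 9.08 CPM and did not pass (0.71 ± 0.29, adjusted p = 0.615). Without the adherent sgNTC PBS replicate 1 library 25 genes were called and without replicate 3 of that group 28. Igtp, Iqgap2, Irgm2, Mrc2, Pfkm, Tap1 and Tgtp1 each lost their call without at least 1 library. With only the compared groups in the fit Gbp2 (adjusted p = 0.086), Irgm2 (0.101), Mrc2 and Iqgap2 lost it.

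In detached sgNTC cells IFN-gamma raised interferon genes, class II pathway genes and Cd274. The GTPase Iigp1 rose from 0.738 to 75.9 CPM (log2 fold change 6.66 ± 0.84, adjusted p = 0.000647, n = 3 each), and Igtp from 9.52 to 99.2 CPM (3.39 ± 0.34, 9.85e-06). Irf1 rose from 48.4 to 131 CPM (1.44 ± 0.09, 6.21e-11). The master regulators of class I and class II genes, Nlrc5 (3.32 ± 0.37, 7.12e-07) and Ciita (3.31 ± 0.47, 1.91e-05), both rose, as did the class II invariant chain Cd74, from 0.997 to 12.5 CPM (3.67 ± 0.43, 3.02e-05). With only the compared groups in the fit Iigp1 (adjusted p = 0.0907), Igtp (0.0758), Cd74 (0.123) and Cd274 (0.141) were not called. Of 300 genes called, 192 rose and 108 fell, with 57 up and 1 down by more than 2-fold. Without a filter on low counts 238 rose and 414 fell, and by DESeq2 259 rose and 235 fell. The interferon lists held 56 of the 192. Genes raised in both cultures numbered 40, where independent lists of these sizes would share 0.56.

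Among detached sgNTC cells, 15 of 17 GTPases rose, and all 17 adjusted over the list alone (camera adjusted p = 1.57e-61). Raised members numbered 20 of 29 in the type I signature, 24 adjusted over the list alone (1.94e-70), and 13 of 20 in class I presentation, 16 adjusted over the list alone (3.82e-40). In the receptor and JAK-STAT list 4 of 16 rose (2.17e-19), in the class II list 4 of 7 (5.47e-08) and among death pathway genes 4 of 26, 8 adjusted over the list alone (4.49e-06). Cd274 (9.61 to 28.9 CPM, 1.59 ± 0.27, adjusted p = 0.00245) and the galectin Lgals9 (0.45 ± 0.09, 0.00511) rose among 16 checkpoint genes (0.00136). These 7 list calls held with an estimated correlation.

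The genes that fell in detached sgNTC cells under IFN-gamma included 6 of 23 hypoxia and glycolysis genes, 12 adjusted over the list alone, such as Aldoa (1684 to 1327 CPM, -0.34 ± 0.06, adjusted p = 0.00013) and Pgk1 (2993 to 2355 CPM, -0.35 ± 0.06, 0.00021). Hexokinase Hk1 (-0.48 ± 0.10, 0.00608) and Gpi1 (-0.47 ± 0.09, 0.00385) fell as well. The stress-response genes Atf5 (-0.47 ± 0.10, 0.00901) and Slc7a5 (-0.38 ± 0.08, 0.00604) fell, 2 of 22 in that list and 7 adjusted over the list alone. The matrix genes Col4a1, Col4a2 and Lamb1 fell by 0.26, 0.26 and 0.36 on the log2 scale. Camera called these 3 lists with adjusted p = 2.58e-13, 8.66e-06 and 0.00215, but they reached 0.0674, 0.157 and 0.157 with an estimated correlation. Another 9 lists were called with the preset correlation only, mitosis (0.447 with an estimated correlation), DNA replication (0.339), complement (0.157) and immediate early genes (0.339) upward, and ferroptosis (0.339), ER chaperones (0.339), integrins (0.22), SRF targets (0.339) and heat shock (0.339) downward. Of these, ER chaperones and SRF targets also lost their call under library totals, at 0.0508 each. Without the ULA sgNTC PBS replicate 2 library 127 genes were called and without the ULA sgNTC IFN-gamma replicate 2 library 166. Of 56 genes named by the naming rule in this comparison, 23 lost their call without at least 1 library, Atf5, Slc7a5, Lgals9, Col4a1, Col4a2, Lamb1 and the class II genes H2-DMa and H2-DMb1 among them. With only the compared groups in the fit 21 lost it, Hk1 (adjusted p = 0.236), Atf5, Slc7a5, Lgals9 and Lamb1 among them.

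**Figure D3:**
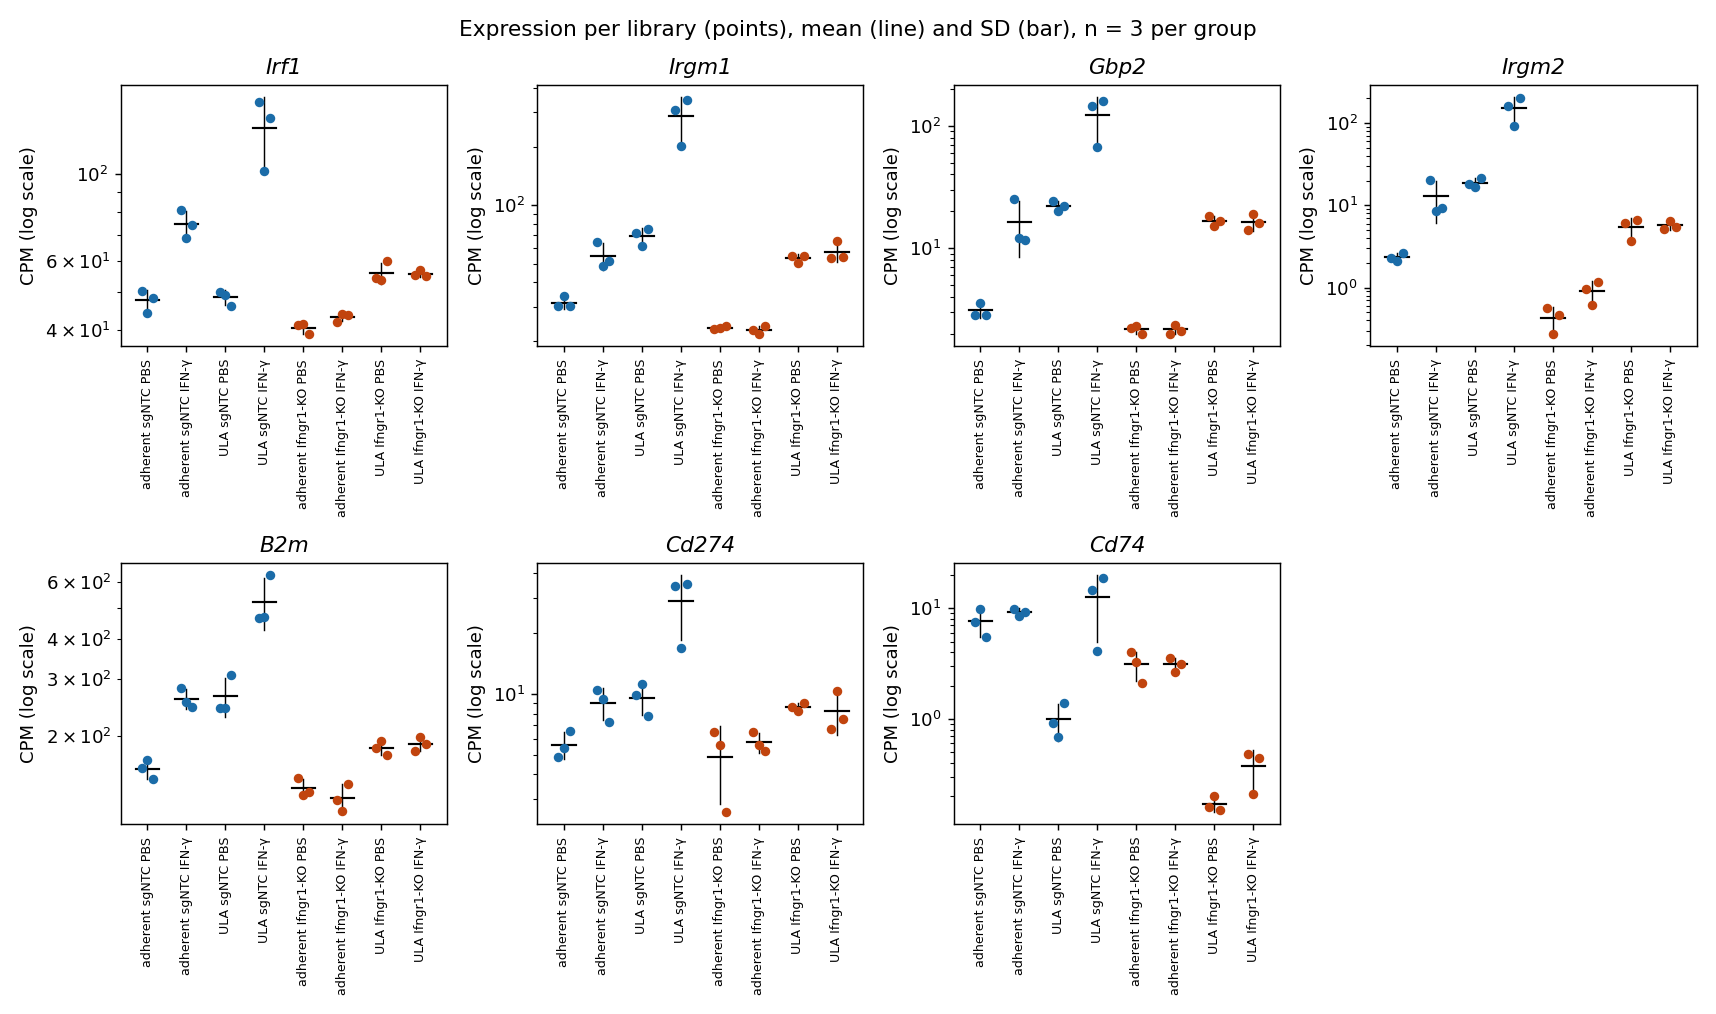
CPM on a log axis of Irf1, Irgm1, Gbp2, Irgm2, B2m, Cd274 and Cd74 in each library by group, with group means and SD. IFN-gamma raised Irf1 from 47.6 to 74.5 CPM in adherent and from 48.4 to 131 CPM in ULA sgNTC cells.

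Whether detached cells respond more strongly was tested as an interaction within the sgNTC line. For 7 genes the response was larger in ULA cells, and for none smaller, by edgeR (781 genes at an unadjusted p under 0.05, 9 genes called by DESeq2). Without a filter on low counts 63 were called, 25 larger and 38 smaller. Cd274 was not called (0.88 ± 0.40, adjusted p = 0.901). Among them were the signalling genes Stat2 (0.89 ± 0.14 on the log2 scale, adjusted p = 0.00753) and Irf1 (0.79 ± 0.13, 0.00753), the GTPase Irgm1 (1.23 ± 0.21, 0.0491), the antiviral genes Samhd1 (0.52 ± 0.09, 0.00753) and Ifit2 (1.26 ± 0.24, 0.0249), and Cd74 (3.39 ± 0.56, 0.0249). All 7 belong to the interferon lists. Cd74 started from 7.6 CPM in adherent and from 0.997 CPM in ULA PBS cells and reached 9.24 and 12.5 CPM. The mean log2 CPM of the 17 GTPases went from -0.28 ± 0.1 to 1.54 ± 0.41 (SD, n = 3) in adherent cells and from 2.04 ± 0.09 to 4.57 ± 0.68 in ULA cells.

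Lists moved in this interaction were the class II list, with Cd74 called and 2 of 7 members adjusted over the list alone (camera adjusted p = 5.5e-05, 0.0436 with an estimated correlation), and 10 lists that were lost with an estimated correlation. Upward these were receptor and JAK-STAT genes (0.0736), GTPases (0.314), the type I signature (0.31), mitosis (0.72), DNA replication (0.314) and immediate early genes (0.314). Downward they were ferroptosis (0.53), hypoxia and glycolysis (0.383), the integrated stress response (0.314) and ER chaperones (0.314). The count rested on single libraries. It was 1 without the ULA sgNTC PBS replicate 3 library, 2 without adherent sgNTC PBS replicate 1, 3 without ULA sgNTC PBS replicate 2, ULA sgNTC IFN-gamma replicate 1 or adherent sgNTC IFN-gamma replicate 3, and 4 without adherent sgNTC PBS replicate 2 or 3, adherent sgNTC IFN-gamma replicate 2 or ULA sgNTC PBS replicate 1. Of the 7 genes, all but Stat2 lost their call without at least 1 library, and a fit of the 4 compared groups alone called 1 gene, Samhd1. Irgm1 also lost its call with the replicate block and with counts halved and rounded.

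Ifngr1-KO cells, the control for IFN-gamma without its receptor, called 1 gene in adherent and 0 in ULA culture by edgeR. The gene was Scaf1, a splicing-related factor, at 89.7 against 71.5 CPM (0.33 ± 0.05, adjusted p = 0.01, n = 3 each), and it lost its call without adherent Ifngr1-KO IFN-gamma replicate 1 or 3 or PBS replicate 1 or 2. The count in adherent cells was 0 without IFN-gamma replicate 1 or PBS replicate 1 or 2, 2 without adherent Ifngr1-KO IFN-gamma replicate 2, 3 without PBS replicate 3, and in ULA cells 5 without Ifngr1-KO IFN-gamma replicate 2. An unadjusted p under 0.05 was reached by 1215 and 1103 genes, DESeq2 called 26 and 1, and 31 and 33 were called without a filter on low counts. Irf1 changed by 0.09 (95% interval -0.1 to 0.28) in adherent and -0.01 (-0.19 to 0.18) in ULA cells. Gbp2 changed by 0 (-0.92 to 0.92) and -0.03 (-0.65 to 0.58). These intervals leave out the sgNTC estimates of the same culture, 0.65 and 1.44 for Irf1 and 2.41 and 2.47 for Gbp2. In adherent Ifngr1-KO cells the intervals of Irgm2 (1.06, -0.52 to 2.64), Cd274 (0.24, -0.39 to 0.87) and Cd74 (0, -0.84 to 0.84) include the adherent sgNTC estimates of 2.47, 0.71 and 0.28.

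No list was called with an estimated correlation in Ifngr1-KO cells treated with IFN-gamma. With the preset correlation SRF targets (camera adjusted p = 0.00635, 0.919 with an estimated correlation) and YAP targets (0.0251, 0.953) moved up in adherent cells, the latter with a median above 0 (0.07) and a mean below it (-0.05). In ULA cells mitosis (0.00264), DNA replication (0.000108, with 5 of 24 raised adjusted over the list alone) and SRF targets (0.00926) moved up and mitochondrially encoded genes (0.0227) down, each at 0.995 with an estimated correlation.

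The receptor dependence of the response was tested as the difference in IFN-gamma effect between the lines. In adherent culture 19 genes differed, 14 with a smaller response in Ifngr1-KO cells, 7 of these in the interferon lists. DESeq2 called 146, 180 were called without a filter on low counts, and 10 with counts halved and rounded. Irf9 (-0.93 ± 0.16, adjusted p = 0.00869), B2m, the light chain of MHC class I (-0.82 ± 0.16, 0.0489), Erap1 (-0.73 ± 0.11, 0.00575) and Casp12 (-0.93 ± 0.19, 0.0316) were among them. The 5 with a larger value were Rhob (0.47 ± 0.09, 0.00887), Scaf1 (0.44 ± 0.08, 0.00869), Hip1r (0.42 ± 0.09, 0.0262), Plec (0.41 ± 0.07, 0.00887) and the myosin Myh9 (0.33 ± 0.06, 0.0218). Of the GTPases 0 of 17 passed but 9 did adjusted over the list alone, beside 6 of 20 class I and 6 of 29 type I genes. Camera called these 3 lists (1.21e-15, 1.46e-11, 3.63e-11), the receptor list (0.000426) and, upward, the matrix, integrin, YAP and SRF lists, but with an estimated correlation they reached 0.0556, 0.0556, 0.0559, 0.0903, 0.33, 0.456, 0.456 and 0.456. The integrin and YAP lists had means just below 0 (-0.02 and 0). The count was 2 without adherent sgNTC PBS replicate 3, 10 without PBS replicate 1, 11 without sgNTC IFN-gamma replicate 3, and 12 without sgNTC IFN-gamma replicate 2 or Ifngr1-KO IFN-gamma replicate 2. All 15 named genes but Irf9 and Erap1 lost their call without at least 1 library, Casp12 and Hip1r also with only the compared groups in the fit. Counts halved and rounded left 5 genes with a smaller response in Ifngr1-KO cells, where 14 were called before, and Casp12 and B2m were among those lost.

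In ULA culture 195 genes differed between the lines in their response to IFN-gamma, 116 with a lower value in Ifngr1-KO cells, and 35 of these lay in the interferon lists. Irf1 differed by -1.44 ± 0.13 (adjusted p = 1.83e-07), Stat2 by -1.38 ± 0.14 (1.28e-06), the immunoproteasome subunit Psmb9 by -5.43 ± 0.87 (0.000724) and Cd274 by -1.66 ± 0.39 (0.0424). Lower values were found for 10 of 17 GTPases, 14 of 29 type I genes, 7 of 20 class I genes and 4 of 16 receptor genes, and for 15, 21, 12 and 4 adjusted over the list alone. These lists and the class II, checkpoint and death pathway lists were called by camera and held with an estimated correlation (0.00185, 0.00129, 0.00708, 0.00236, 0.0374, 0.0374 and 0.0374). Higher values were found for Aldoa (0.41 ± 0.08, adjusted p = 0.00343), Eno1 (0.38 ± 0.09, 0.0175) and Atf5 (0.60 ± 0.14, 0.0292). Another 10 lists were called with the preset correlation and reached 0.135 for complement, 0.334 for hypoxia and integrins, 0.333 for the stress response and immediate early genes, 0.359 for ER chaperones, 0.143 for matrix, 0.164 for SRF targets, 0.39 for heat shock and 0.37 for autophagy with an estimated correlation. The autophagy list also lost its call with RLE factors (0.05) and library totals (0.0901). Scaling by library total moved the split from 79 higher and 116 lower to 55 and 151, and leaving out the filter on low counts to 304 and 220 of 524. DESeq2 called 501. The count was 75 without the ULA Ifngr1-KO PBS replicate 1 library, 78 without ULA sgNTC PBS replicate 2 and 280 without ULA Ifngr1-KO IFN-gamma replicate 2. Of 40 named genes 21 lost their call without at least 1 library, Cd274, Eno1 and Atf5 among them. Cd274 and Atf5 also lost it with only the compared groups in the fit.

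Detachment without IFN-gamma changed most of the measured transcriptome of sgNTC cells. ER chaperones fell together, the lumenal chaperone Hspa5 from 9388 to 783 CPM (log2 fold change -3.58 ± 0.06, adjusted p = 8.32e-33, n = 3 each) and Pdia4 from 1832 to 167 CPM (-3.46 ± 0.06, 8.32e-33). Amino acid stress genes fell too, among them Chac1 (-5.07 ± 0.10, 2.75e-29), the asparagine synthetase Asns (516.9 to 68.3 CPM, -2.92 ± 0.06, 5.74e-29) and the stress hormone Fgf21 (-6.74 ± 0.25, 1.37e-16). The acute-phase protein haptoglobin (Hp) rose from 3.7 to 257 CPM (6.13 ± 0.17, 1.94e-17), Txnip from 8.67 to 452 CPM (5.69 ± 0.21, 5.28e-14) and the aldehyde oxidase Aox3 from 20.8 to 714 CPM (5.10 ± 0.17, 4.85e-15). The lipase Pnliprp1 had no count in adherent PBS cells and 13 CPM in ULA cells, 548-fold higher against a floor of 3 counts over the group. Of 14622 genes 9446 (64.6%) changed, 4747 up and 4699 down, with 2015 and 1197 beyond 2-fold, and 5367 up and 4015 down under library totals.

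All 16 ER chaperones and 21 of 22 integrated stress response genes fell in detached sgNTC cells (camera adjusted p = 4.92e-71 and 1.63e-39), and 8 of 9 complement genes rose (8.95e-07), such as C3 from 38 to 319 CPM (3.07 ± 0.11, adjusted p = 1.69e-16). These 3 list calls held with an estimated correlation. Interferon genes rose without added IFN-gamma. All 29 type I signature genes rose (8.23e-09, 0.0804 with an estimated correlation), including the RNA sensor pathway gene Oas2 from 1.64 to 36 CPM (4.49 ± 0.19, adjusted p = 2.91e-19). GTPases had 13 of 17 raised (0.533 with an estimated correlation) and receptor and JAK-STAT genes 12 raised and 2 lowered (0.191). Class I presentation, with 12 raised and 3 lowered, and class II, with 2 and 1, were not called (camera adjusted p = 0.7 and 0.839). The lowered class I members included the ER chaperones Calr (-2.467 to -2.346 over the settings tried) and Canx (-1.029 to -0.908). The mean log2 CPM of the class I list still went from 4.85 ± 0.06 to 5.34 ± 0.02 (SD, n = 3). Cholesterol synthesis had 20 of 22 lowered (0.0545 with an estimated correlation), for example Lss from 239 to 29.3 CPM (-3.03 ± 0.08, 1.96e-26), DNA replication 19 of 24 (0.289), mitosis 20 of 24 (0.578) and p53 targets 10 of 17 with 4 raised (0.0545). All 13 mitochondrially encoded genes rose (0.191), mt-Cytb by 1.27 ± 0.07 (2.35e-17). Camera called these lists with the preset correlation only.

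The remaining lists were not called by camera in detached sgNTC cells. Raised and lowered members numbered 16 and 1 of 23 for hypoxia and glycolysis (adjusted p = 0.0644, 0.0483 under library totals), 13 and 5 of 21 for autophagy and lysosome (0.105, 0.0483 under library totals), and 13 and 0 of 20 for oxidative phosphorylation (0.186). They were 10 and 5 of 23 for matrix, 11 and 4 of 24 for integrins, 9 and 9 of 19 for YAP targets, with Ankrd1 at -3.12 ± 0.05 (2.47e-32), and 9 and 5 of 18 for SRF targets. For epithelial and mesothelial genes they were 8 and 2 of 12, for mesenchymal genes 2 and 4 of 11, for stemness genes 5 and 1 of 9, and for CDK inhibitors and cyclin D 8 and 2 of 11, with Ccnd1 at -1.77 ± 0.06 (3.52e-24). Chemokines had 6 and 1 of 9, checkpoints 9 and 1 of 16, NF-kB targets 6 and 8 of 17, death pathway genes 11 and 10 of 26, ferroptosis 6 and 7 of 18, fatty acid metabolism 10 and 7 of 19, immediate early genes 8 and 4 of 15 and heat shock genes 7 and 5 of 13. Markers of other cell types were few. Macrophage markers had 3 raised and 1 lowered of 4 tested (Cd68 3.33 to 6.95 CPM), lymphocyte 1 raised of 2, endothelial 2 of 4 (Vwf 5.29 to 24.9 CPM), fibroblast and pericyte 1 of 5 (Dcn 47.7 to 97.3 CPM) and erythroid 1 of 2. Adjusted over the list alone the counts were the same except for hypoxia and glycolysis, with 17 raised, and heat shock, with 8 raised. Scaling by library total shifted the median of all genes in this comparison to 0.128, from 0.031 under TMM.

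**Figure D4:**
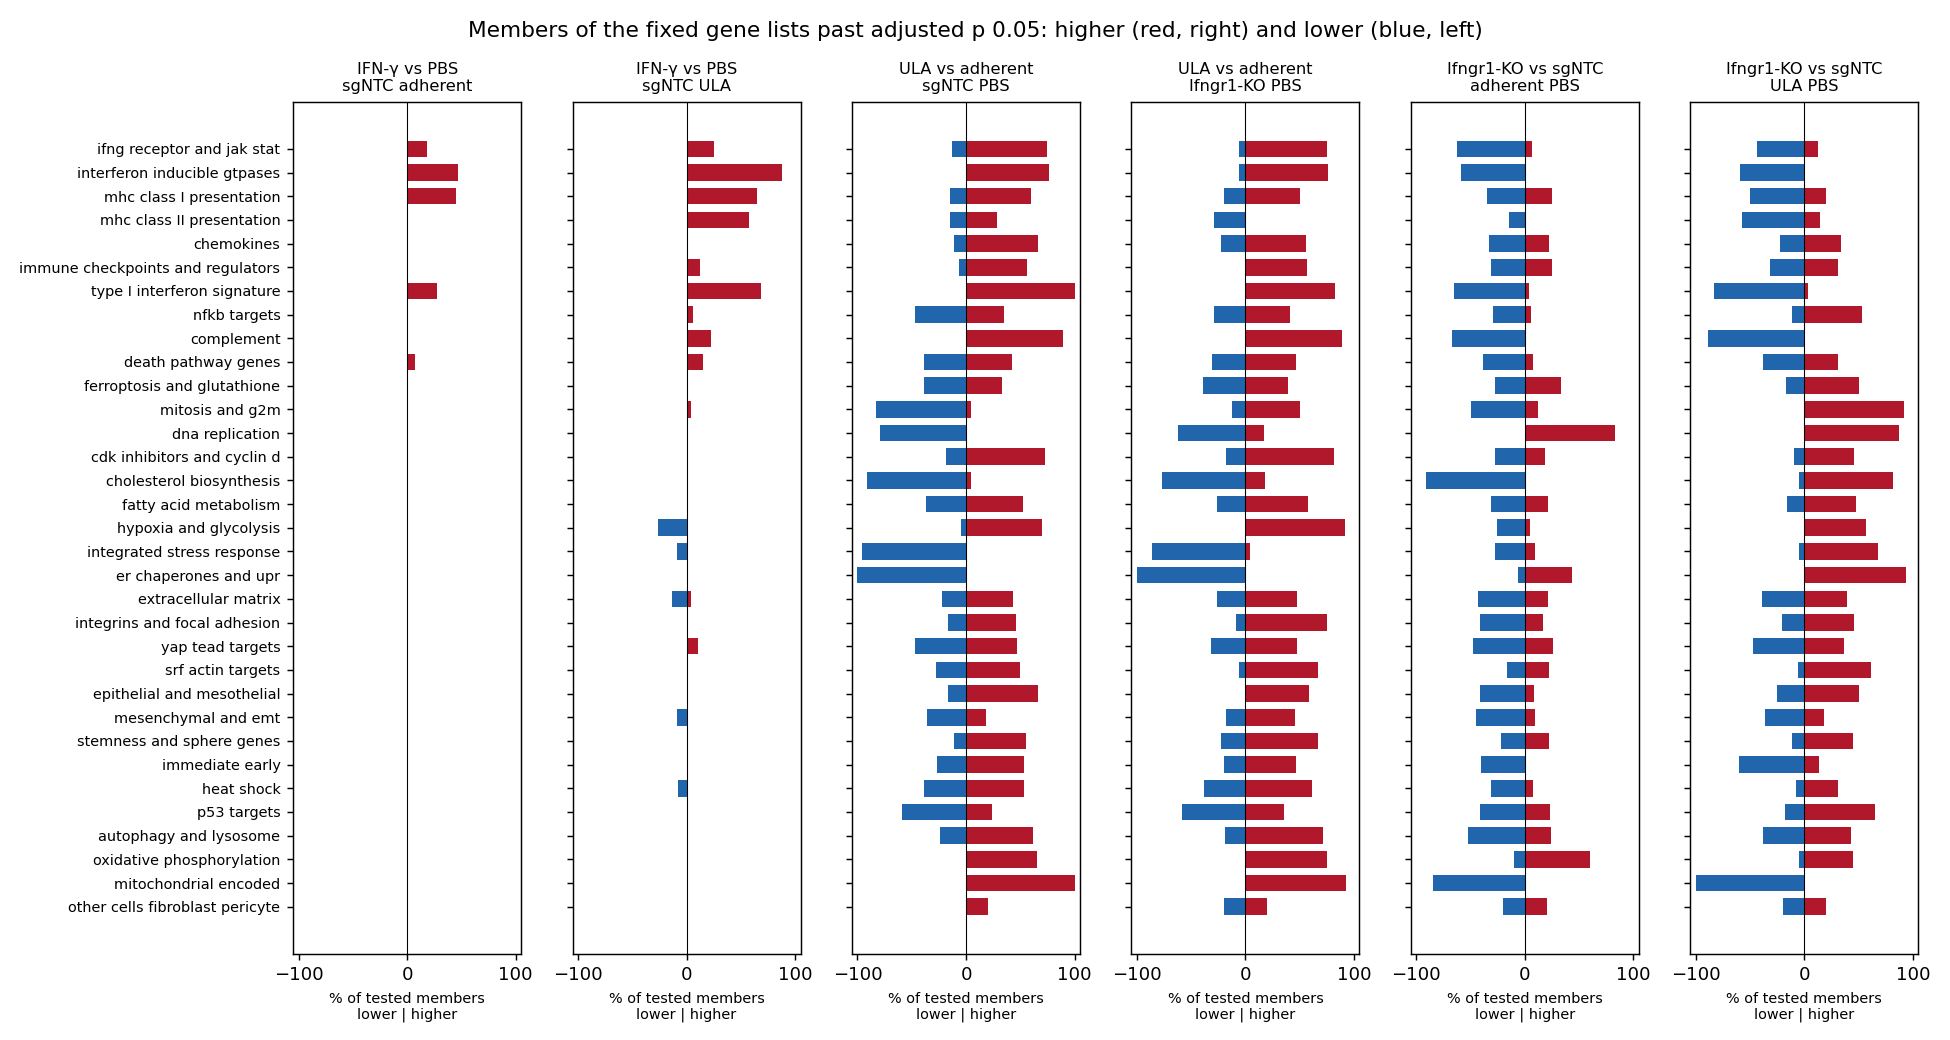
Percent of the tested members of each fixed gene list called higher or lower in 6 comparisons. In ULA against adherent sgNTC cells all 16 ER chaperones are lower and all 29 type I signature genes higher.

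Ifngr1-KO cells changed in the same direction on detachment for most genes. Hspa5 fell from 9996 to 1443 CPM (-2.79 ± 0.05, adjusted p = 4.81e-30, n = 3 each) and the stress transcription factor Ddit3 from 318 to 21.3 CPM (-3.90 ± 0.09, 2.22e-25). The mucin Muc4 rose from 4.5 to 200 CPM (5.48 ± 0.15, 1.17e-18), the adhesion molecule Ceacam1 from 7.09 to 201 CPM (4.82 ± 0.13, 1.86e-19) and the oxygen-sensing hydroxylase Egln3 from 56.9 to 389 CPM (2.77 ± 0.13, 1.82e-13). In all 8870 genes changed (60.7%), 4327 up and 4543 down, with 1676 and 994 beyond 2-fold, and 4589 up and 4218 down with RLE factors. Of 7234 genes called in both lines 6902 (95.4%) moved the same way. Fold changes in the lines, which share no library, correlated across genes at Pearson's r = 0.696 and Spearman's rho = 0.721, and genes are not independent replicates. Independent lists would share 1405 raised and 1460 lowered genes, and 3309 and 3593 were shared.

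All 16 ER chaperones fell in detached Ifngr1-KO cells, 19 of 22 stress response genes fell with 1 raised, 8 of 9 complement genes rose, and 7 of 12 epithelial and mesothelial genes rose, such as Wt1 (1.51 ± 0.06, 5.19e-22) and Krt19 (1.78 ± 0.10, 1.03e-12). These 4 lists were called with the preset correlation (4.73e-66, 2.08e-23, 6.89e-08 and 0.000946) and held with an estimated correlation (2e-06, 0.00444, 0.00444 and 0.0489). Type I signature genes rose in 24 of 29 (25 adjusted over the list alone), GTPases in 13 of 17 with 1 lowered, and receptor genes in 12 of 16 with 1 lowered, in cells with reduced Ifngr1. With an estimated correlation these lists reached 0.0913, 0.431 and 0.0913. The other lists called with the preset correlation only were checkpoints (0.0977 with an estimated correlation), DNA replication (0.367), cholesterol synthesis (0.475), hypoxia and glycolysis (0.274), matrix (0.171), integrins (0.0913), SRF targets (0.175), stemness (0.0977), autophagy (0.266) and mitochondrially encoded genes (0.196). Hypoxia and glycolysis had 21 of 23 raised, integrins 18 of 24 with 2 lowered, and cholesterol synthesis 17 of 22 lowered with 4 raised. Macrophage markers had 3 of 4 raised, with Cd68 from 6.38 to 17.9 CPM.

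Differences between the lines in PBS were wide before any IFN-gamma was added. In adherent culture the Ifngr1-KO line had more of the matrix peroxidase Pxdn (10.5 against 0.806 CPM, 3.75 ± 0.19, adjusted p = 9.52e-18, n = 3 each), the ligand Wnt7b (8.6 against 0.669 CPM, 3.69 ± 0.25, 2.29e-14) and the chemokine Ccl2 (5.52 against 0.502 CPM, 3.38 ± 0.34, 3.41e-09). It had less of the complement regulator Cd55 (47.1 against 374 CPM, -2.99 ± 0.07, 4.85e-27). Xist, the RNA that silences an X chromosome, stood at 0.0971 against 223 CPM. The sulfotransferase Hs6st2, Soga3 and the matrix gene Hmcn1 had no count in these Ifngr1-KO libraries. Against a floor of 3 counts over the group they were 441-fold, 214-fold and 215-fold lower. Of 14622 genes 6421 (43.9%) differed, 2932 higher and 3489 lower, with 352 and 870 beyond 2-fold. Scaling by library total turned the split to 3623 higher and 3027 lower.

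Complement was the list that held with an estimated correlation between the adherent lines, with 6 of 9 lower (camera adjusted p = 5.02e-13, 0.000747). Interferon genes were lower at baseline in the Ifngr1-KO line, with 19 of 29 type I genes lower and 1 higher (0.254 with an estimated correlation), 10 of 17 GTPases (0.617) and 10 of 16 receptor genes (0.254). The ubiquitin ligase Rnf213 was at 152 against 450 CPM (-1.56 ± 0.07, adjusted p = 1.6e-16). Class I genes went both ways, 5 higher and 7 lower (8 adjusted over the list alone). The mesenchymal list was not called (camera adjusted p = 0.0668) but was called downward under library totals (0.0466). DNA replication had 20 of 24 higher (0.254), for example Cdc6 (0.85 ± 0.08, 8.66e-11), cholesterol synthesis 20 of 22 lower (0.468) and mitochondrially encoded genes 11 of 13 lower (0.468). Vwf, an endothelial marker, stood at 30.9 against 5.29 CPM, and Dcn, a fibroblast marker, at 17.2 against 47.7 CPM.

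In ULA culture 7320 genes (50.1%) differed between the lines, 3584 higher and 3736 lower in Ifngr1-KO cells, with 394 and 1144 beyond 2-fold, and 3769 higher and 3604 lower with RLE factors but 3164 higher and 4085 lower under library totals. Pxdn (3.98 ± 0.16, adjusted p = 7.66e-21), Wnt7b (4.34 ± 0.26, 6.48e-16) and the clotting factor F13a1 (254 against 24.8 CPM, 3.36 ± 0.10, 8.31e-19) were higher, as was the hyaluronan receptor Cd44 (552 against 188 CPM, 1.55 ± 0.05, 2.21e-22). The growth-arrest gene Gas1 had no count in Ifngr1-KO PBS cells against 51.2 CPM. Against a floor of 3 counts over the group Gas1 was 1990-fold, Hmcn1 507-fold and Hs6st2 258-fold lower. Genes higher in Ifngr1-KO cells in both cultures numbered 1631 and genes lower in both 2099, where independent lists would share 719 and 891.

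Proliferation and biosynthesis genes were higher in detached Ifngr1-KO than in detached sgNTC cells, with 22 of 24 mitosis genes (Mki67 0.91 ± 0.07, adjusted p = 2.66e-13), 21 of 24 DNA replication genes (22 adjusted over the list alone), and 18 of 22 cholesterol synthesis genes with 1 lower (Sqle 1.22 ± 0.05, 1.69e-20). With an estimated correlation these lists reached 0.235, 0.0697 and 0.25. Higher members numbered 15 of 16 for ER chaperones (0.0697 with an estimated correlation) and 15 of 22 for the stress response, 16 adjusted over the list alone (0.0697). Complement had 8 of 9 lower (camera adjusted p = 7.24e-11) and held at 0.00222. The type I signature had 24 of 29 lower and 1 higher (1.14e-09, 0.0697 with an estimated correlation) and GTPases 10 of 17 lower (0.00286, 0.358). The receptor and JAK-STAT list was not called (0.0515) but was under library totals (0.0436). Ferroptosis (0.376), fatty acid metabolism (0.225), hypoxia and glycolysis (0.57), integrins (0.271) and SRF targets (0.25) moved up and mitochondrially encoded genes (0.182) down with the preset correlation only. Markers of other cell types went both ways. Cd68, a macrophage marker, stood at 17.9 against 6.95 CPM. Csf1r and Egfl7 were also higher and Cspg4 lower, each losing its call under some alternatives.

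The medians of chromosome 10, which carries Ifngr1, and of chromosome 18 were shifted downward in the Ifngr1-KO line. The median log2 fold change between the lines over 701 tested genes of chromosome 10 was -0.51 in adherent PBS, -0.49 in adherent IFN-gamma, -0.45 in ULA PBS and -0.44 in ULA IFN-gamma cells. Over 366 genes of chromosome 18 it was -0.46, -0.51, -0.39 and -0.39. Smaller shifts in the same 4 settings, in that order, were found for chromosome 1 (-0.25, -0.28, -0.23 and -0.29) and chromosome 8 (-0.26, -0.23, -0.25 and -0.23).

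**Figure D5:**
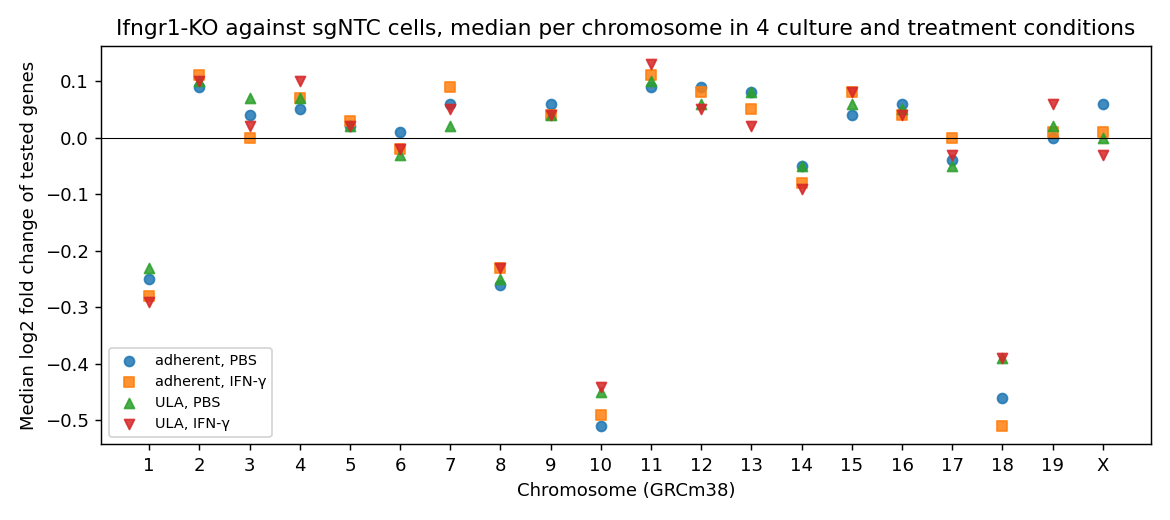
Median log2 fold change of Ifngr1-KO against sgNTC over the tested genes of each chromosome, in 4 culture and treatment settings. Chromosome 10 (-0.51 to -0.44) and chromosome 18 (-0.51 to -0.39) lie lowest in every setting.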

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

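The tests of scaling, of handling and of Ifngr1 for the larger ULA response, of admixture in the replicate 2 library, of library scaling for the chromosomes, and the splits of the sgNTC ULA and ULA minus adherent results were chosen only after the result was seen.

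The effect of IFN-gamma differed between cultures within the sgNTC line for 7 genes, by an interaction test. In 100 splits of these libraries 8 gave at least 7 genes. The highest other split, with 376, reverses the treatment labels in 1 culture, and the highest of the rest gave 104. Splits that call many times the real count point to a structure of the samples, here the response of both cultures, which mixed labels carry into the interaction. These splits therefore neither exclude chance for the count nor measure it.

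More genes were called for IFN-gamma in detached than in adherent sgNTC cells, 300 against 46. Thinned to 33494774 counts per library the counts were 289 and 48, which argues against depth, and all 7 genes of the interaction were still called under both other scalings. The median change of these 7 genes was -0.006 in Ifngr1-KO ULA cells (-0.5 to 1.141, the highest Cd74), against 1.435 in sgNTC ULA cells (0.642 to 3.673, the highest Cd74). As a set these genes, picked for a large sgNTC ULA response, did not rise in the Ifngr1-KO line. Handling shared by IFN-gamma and PBS wells cancels in this contrast, so these values do not test it. Ifngr1 was lower in ULA cells (-0.279), against a larger supply of its mRNA, while Ifngr2, the signalling chain, was higher (0.403), as were 4747 genes, so more Ifngr2 may contribute but is a weak candidate explanation. Expression before treatment also differed, with the mean of the 17 GTPases at -0.28 log2 CPM in adherent and 2.04 in ULA sgNTC PBS cells. Whether that difference raised the number of calls in ULA cells was not tested. A larger count is thus not by itself a larger response. Dead cell removal and other effects of detachment were confounded with culture and stay open. The 10 splits are too few for a share under 0.05 (adherent 46 against a highest other of 0, ULA 300 against 23).

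Within the ULA sgNTC IFN-gamma group the replicate 2 library differed from the other 2 by a median of -0.382 log2 over 88 induced genes, 3 of them higher. These were called genes past a minimum rise, with a mean of at least 5 CPM in the other 2 libraries alone. That choice favours genes high in those 2 libraries and can widen the difference. The replicate 2 median over all tested genes, -0.0052, is held near 0 by the scaling itself and so does not test scaling of that library. Unexposed cells mixed into that culture would lower every list by 1 share. The library kept a median of 40.9% of the rise in GTPases (interquartile range 34.9% to 44.9%) and 68% in type I genes (58.7% to 80%), ranges that do not overlap. Class I genes kept 46.9% (42.3% to 50.8%), which overlaps the GTPases, and receptor and JAK-STAT genes 58.9% (51.5% to 63.3%). The shares were thus unequal, but they come from 1 library and take the rise from the mean of the PBS wells. A mixture is therefore not excluded. A weaker or later exposure of that well was not tested and stays open.

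The effect of IFN-gamma differed between the lines for 19 genes in adherent and 195 genes in ULA culture, by interaction tests. Of 100 splits 3 gave at least 19 genes, with a highest other of 37, and 1, the real one, gave at least 195, with a highest other of 128, both shares under 0.05. These splits mix labels as those above do, so chance is not taken as excluded, and the 19 became 2 without the adherent sgNTC PBS replicate 3 library and 10 with counts halved and rounded, and the 195 became 75 without ULA Ifngr1-KO PBS replicate 1 and 78 without ULA sgNTC PBS replicate 2. Within Ifngr1-KO cells 10 splits are too few for a share under 0.05. There 5 of 10 splits gave at least the 1 gene of adherent cells, with a highest other of 14, and all 10 gave at least the 0 genes of ULA cells, with a highest other of 6.

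The effect of culture differed between the lines for 4068 genes, by an interaction test added after the data were seen. In 100 splits 12 gave as many. The highest, 10302, reversed the culture labels in 1 line, and the highest of the rest gave 7456, which points to the large shared effect of culture entering the interaction when labels are mixed. These splits therefore neither exclude chance for the count nor measure it, and with each library left out the count was 3516 to 3999. For the culture effects (9446 in sgNTC and 8870 in Ifngr1-KO cells) and the line effects (6421 adherent and 7320 ULA), 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many, with a highest other of 0 in each.

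Genes of chromosomes 10 and 18 were lower in the Ifngr1-KO line, with a median below that of all genes in each of 3 classes of gene length (at its nearest -0.425), which argues against gene length. The difference was -0.475 at its nearest to 0 over 3 scalings, which does not test library scaling, since a factor per library moves every chromosome alike. A copy number difference between the lines may underlie it. In all 4 settings 100% of the 12 bins of 20 Mb on these chromosomes had a median below -0.2, so the shift ran along both. The share was 9.3% to 12.4% of 129 bins elsewhere, chromosomes 1 and 8 included. Those bins were no even background. All 15 below -0.2 in adherent PBS, all 12 in adherent IFN-gamma and all 14 in ULA PBS cells lay on chromosomes 1 and 8. Of the 16 in ULA IFN-gamma cells, the only ones on other chromosomes lay on 6, 14 and X, each at -0.21. Chromosomes 10 and 18 were picked for their low medians in these same data, so the contrast with the other bins is no independent support. The medians of chromosomes 1 and 8 were also lower in all 4 settings, by less. No DNA was measured in the data used here, so this remains a hypothesis. It would lower Ifngr1 on chromosome 10 as well, whose fall of 1.46 in adherent cells lies beyond the chromosome's median of -0.51.

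Of the 9 transgenes in the annotation 4 had counts in every library. The lowest count in any library was 5216 for mCherry, 1720 for RFP, 2533 for Cas9 and 4178 for PuroR. ZsGreen, EGFP, the blasticidin gene, Cre and DTR had 0 counts in all 24 libraries.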

How the results depend on the processing

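Counts halved and rounded, and all fits of the culture by line difference, were chosen only after the data were seen. The fall of Ifngr1 kept its direction and call under every alternative, -1.495 to -1.405 in adherent and -1.321 to -1.193 in ULA cells with 1 library left out, and so did the counts for culture and line, which stayed within 1.5 times of the reported ones. Their split between higher and lower was less steady. Library totals gave 3623 higher and 3027 lower for line in adherent cells, 3164 and 4085 for line in ULA cells, and 5367 and 4015 for culture in sgNTC cells. For line in ULA cells and culture in Ifngr1-KO cells RLE factors, DESeq2 and the missing filter turned a near even split. Over all settings, 12725 of 13210 values of named genes stayed on their side of the threshold, 485 became weaker and 0 reversed, 404 of the 485 with 1 library left out and 46 with only the compared groups in the fit.

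The smaller counts moved. Without a filter on low counts, where more genes near 0 are tested, the counts for IFN-gamma were 175 (sgNTC adherent), 652 (sgNTC ULA), 31 (Ifngr1-KO adherent) and 33 (Ifngr1-KO ULA), and for the interactions 63 (ULA minus adherent), 180 (Ifngr1-KO minus sgNTC, adherent) and 524 (ULA). DESeq2 gave 83, 494, 26 and 1 for IFN-gamma, and 146 and 501 for the differences between lines. With only the compared groups in the fit, 101 genes were called in sgNTC adherent, 0 in Ifngr1-KO adherent, 1 in Ifngr1-KO ULA and 1 in the ULA minus adherent interaction. Counts halved and rounded gave 10 for Ifngr1-KO minus sgNTC in adherent cells. The cause was not tested. RLE factors, library totals and the filter of 1 CPM in 3 libraries kept every count of these comparisons within 1.5 times.

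With each library left out the counts ran from 25 to 40 (sgNTC adherent), 127 to 346 (sgNTC ULA), 0 to 3 (Ifngr1-KO adherent), 0 to 5 (Ifngr1-KO ULA), 1 to 7 (ULA minus adherent), 2 to 22 and 75 to 280 (Ifngr1-KO minus sgNTC, adherent and ULA), 8839 to 8987 and 8300 to 8595 (culture in sgNTC and Ifngr1-KO), and 5556 to 5969 and 6669 to 6930 (line in adherent and ULA cells).

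The replicate block gave 49, 296, 1 and 0 genes for IFN-gamma, 5, 22 and 207 for the interactions, 9416 and 8833 for culture, 6385 and 7328 for line, and -1.465 and -1.273 for Ifngr1. The labels do not say that a number marks a shared batch. Deviations of the 84 same-numbered pairs correlated between -0.061 and 0.06 with a mean of 0.003, and 7 of 24 libraries correlated best with their own number. No sign of a shared batch was seen, which does not exclude one.

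Of 363 list tests, camera called 118 with the preset correlation and 29 with an estimated one, which widens the test by the correlation among members. Fry called 141, RLE factors gave 117, library totals 119 and the replicate block 120, and none reversed. The block changed 4 list calls. With 3 libraries per group, a 1.5-fold difference between responses was recovered in 65.7% of simulated genes in the ULA minus adherent interaction. Those genes were drawn at random among expressed genes. Recovery among interferon genes, some with a wide SE (Gbp2 response 0.35 in adherent and 0.28 in ULA sgNTC cells), was not measured apart and may be lower. Smaller differences were not simulated.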

Other observations

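The difference between the lines in the effect of culture, with its alternatives, and the search for genes absent from 1 line were chosen only after the data were seen.

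Detachment lowered cholesterol and stress response genes less in the Ifngr1-KO line than in the sgNTC line, measured in PBS. Of 24 mitosis genes it raised 12 and lowered 3 in the Ifngr1-KO line, and raised 1 and lowered 20 in the sgNTC line. For the cholesterol synthesis gene Sqle the effect differed by 1.48 ± 0.07 on the log2 scale (edgeR adjusted p = 2.38e-17), for the proliferation marker Mki67 by 1.09 ± 0.09 (7.54e-11), for Asns by 1.11 ± 0.09 (3.14e-12) and for mesothelin (Msln) by 1.13 ± 0.07 (3.68e-15). Of the 4068 genes called, 2426 had a higher and 1642 a lower value in Ifngr1-KO cells, and scaling by library total gave 1706 and 2356. Higher values were found for 20 of 22 cholesterol synthesis genes, 17 of 22 stress response genes (19 adjusted over the list alone) and 8 of 12 epithelial and mesothelial genes (9 adjusted over the list alone), and these lists held with an estimated correlation (adjusted p = 0.0107, 0.0107 and 0.0131). Mitosis, with 23 of 24 higher, and ER chaperones, with 12 of 16, reached 0.0588 each. Another 10 lists were called upward with the preset correlation only, with NF-kB targets at 0.12, ferroptosis at 0.319, DNA replication at 0.428, CDK inhibitors and cyclin D at 0.222, fatty acid metabolism, SRF targets and stemness at 0.1, hypoxia at 0.374, matrix at 0.267 and integrins at 0.0801.

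The effect of culture correlated between the lines across genes at 0.696, from separate libraries, as an effect of culture shared by the lines would give. Dead cell removal from the ULA wells of both lines could give such a correlation as well, so it cannot tell culture from that step.

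In 10 genes the Ifngr1-KO line had group means under 0.3 CPM in all 4 settings and the sgNTC line at least 5 CPM in all 4, and in 0 genes the reverse. They were Xist (at most 0.153 CPM against 223 to 381), Gas1 (0.126 against 18.9 to 52.2), Cacna2d2 (0.0539 against 22.1 to 32.4), Dab2ip (0.0696 against 11.3 to 20.9), Dsg2 (0.0341 against 9.59 to 25.6), Ptpn13 (0.0696 against 7.02 to 20.9), Pkia, Hs6st2, Hmcn1 and Soga3.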
